A study of Ambystoma mexicanum with 12 samples.

How the data were processed

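Gene expression was measured on Affymetrix arrays, in regenerating forelimb blastemas of juvenile axolotls (Ambystoma mexicanum). A blastema is the mound of proliferating cells that forms on a limb stump and rebuilds the lost part. Per the labels' protocols, forelimbs were cut through the distal zeugopod (the lower arm), animals were kept in a drug or its vehicle from day 7 to day 14 after amputation, and blastemas with little stump tissue were taken on day 14. The 3 treatments were DMSO (the vehicle), retinoic acid (RA, the natural ligand of the retinoic acid receptors) and LE135 (by general knowledge a synthetic antagonist of retinoic acid receptor beta). Each treatment had 16 animals, 48 in all, and each of its 4 samples pooled single forelimbs from 4 animals, so the 12 samples were independent pools. The doses were not given in the sources used here.

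The values analysed were the deposited log2 expression values of 20080 probe sets on 12 arrays, 1 array per sample, which the submitters' processing notes credit to RMA (background correction, quantile normalization and probe summarization). The version of RMA was not given in the sources used here. Array medians lay between 6.61 (DMSO 3 and LE135 2) and 6.70 (RA 1 and LE135 4). No 2 arrays held identical values, and pairwise correlations across probe sets ran from 0.973 to 0.998. The 45 Affymetrix control probe sets were left out, which left 20035 for testing. No detection calls were used, so no probe set was removed as background. For arrays, the number of samples limits the precision, and that number was 4 per group.

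Gene names came from the platform's annotation. Of the tested probe sets, 10951 had 1 gene symbol, none had several and 9084 had none. The 8639 distinct symbols were all found in the RefSeq gene table of the species. No coordinates were used. Where a gene had several probe sets, the probe set with the highest mean over all 12 samples stood for it. Disagreement between probe sets was recorded for the genes of largest change and the fixed genes described below. It was not looked up for the list members named in addition.

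All 12 samples entered a single linear model in limma 3.58.1 (R 4.3.3) with a mean per treatment, so that the groups shared an estimate of the spread. A moderated F test compared the 3 treatments, and moderated contrasts compared RA with DMSO, LE135 with DMSO and RA with LE135. Benjamini-Hochberg adjustment was made over all tested probe sets at a threshold of 0.05, and adjusted p below refers to these tests unless another is named. The threshold and the 1.5-fold limit were those of the study's design text, which gives an ANOVA without naming its software. Standard errors (SE) are those of the moderated contrasts unless another is named. The words rose, fell and changed are used of genes that passed this threshold.

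Fixed before the data were examined were the tests, the gene lists, the alternatives and the rule for the genes named. That rule took, for each drug against DMSO, the 12 genes with the largest rise and the 12 with the largest fall among those past the threshold whose 4 samples did not overlap with the 4 of the other group, and up to 8 in each direction for RA against LE135. It added up to 4 members of each described list with the smallest p, and 10 genes whatever their values (RARA, RARB, RARG, CYP26A1, CYP26B1, MEIS1, MEIS2, HOXA13, SHH and FGF8). CRABP2, MSX2, BMP7, EPHA7 and DSC2 fell outside the rule and were named after their values were seen, to complete short counts. LMO1, LHX2 and LHX9 are also given in the comparisons in which they did not pass. UPK3A and UAP1 are also given under RA, outside the rule and the counts of named genes.

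The 29 lists were retinoid metabolism and receptors, proximal limb, distal limb, FGF pathway, hedgehog pathway, WNT pathway, BMP and TGF-beta pathway, extracellular matrix, matrix proteases and inhibitors, cell cycle, ribosomal proteins, oxidative phosphorylation, cholesterol biosynthesis, xenobiotic and oxidative stress response, heat shock and unfolded protein response, interferon response, inflammation, epidermis, secretory epidermis and ion transport, connective tissue fibroblast, cartilage and bone, skeletal muscle, erythrocyte, macrophage and neutrophil, lymphocyte, endothelium, pericyte and smooth muscle, Schwann cell and nerve, and pigment cell. They were written from general knowledge and are not from these samples. Each was tested with limma's camera, which compares a list with all other genes, at a preset correlation of 0.01 between genes, with Benjamini-Hochberg adjustment over the 29 lists. Camera was repeated with the correlation estimated from the data, and limma's fry was run in its place. For each list the members past the threshold are counted over all probe sets and adjusted over the list alone. A list score per sample is the mean over members of the log2 value minus the gene's mean over the 12 samples.

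The 3 treatments share the sample numbers 1 to 4, and no label says that a number marks a shared day or batch. Deviations from the group means were correlated between samples of the same number. Between LE135 and DMSO all 4 correlations were positive, from 0.126 to 0.607, which met the rule set beforehand (over 0.1 in every pair). An alternative fit was therefore made with the number as a block, over all 12 samples. The pairing of LE135 with DMSO comes from the data alone, and an LE135 sample correlated best with the DMSO sample of its own number in 1 of 4 cases. Among samples 1 to 3 of these groups, r was 0.126 to 0.322 at the same number and 0.118 to 0.393 at different numbers. Only pair 4, at 0.607, stood out. Between RA and DMSO the lowest correlation at the same number was 0.0397, and between RA and LE135 it was -0.175. The RA samples thus did not meet the rule, although the block included them.

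Alternatives were an ordinary ANOVA and contrasts without moderation, a trended robust prior, quantile normalization made again, arrays shifted to a common median, removal of the dimmest 25% or 50% of probe sets, array weights, the replicate block, other fold limits, a fit of the 8 compared samples alone, the mean of all probe sets of a gene, a rank correlation of the responses, and the omission of each sample in turn. Leaving out both DMSO 4 and LE135 4, and keeping the control probe sets, were chosen after seeing the data. To judge the correlation of the 2 responses, which share the DMSO samples, unchanged groups were simulated 100 times from the residual arrays in random order, and the DMSO samples were also divided between the comparisons in 6 ways. The analysis was tested on simulated data made from the measured mean and residual SD of each of the 20035 probe sets, with normal and independent noise. For RA against DMSO it recovered 68.7% of 1.5-fold, 80.6% of 2-fold and 95.5% of 4-fold changes, and for LE135 against DMSO 62.7%, 85.1% and 97%.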

Results

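The data set holds 12 arrays of axolotl forelimb blastemas, 14 days after amputation, 4 each after treatment with DMSO, RA or LE135. By the study's design text, limbs treated with DMSO go on to regenerate normally, limbs treated with RA duplicate along the proximodistal axis, and limbs treated with LE135 end truncated. The comparisons ask which transcripts differ between these blastemas. Among all 20035 probe sets, 537 differed among the 3 treatments (limma moderated F test, adjusted over all probe sets), and 329 of them also differed more than 1.5-fold from DMSO in either drug. The design text gives 533 and 327. In 156 of the 329 both drugs passed 1.5-fold, in the same direction in all 156, while 103 did so under RA and not LE135 and 70 under LE135 and not RA.

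DMSO 4 and LE135 4 stood apart from their groups. The mean correlation with the other 3 samples of the group was 0.978 for DMSO 4 and 0.986 for LE135 4, against 0.989 to 0.996 for the other 10. Without both samples, an alternative chosen after seeing the data, 1478 probe sets differed among the treatments and 575 also passed 1.5-fold. Leaving out RA 1 alone lowered these counts to 261 and 195.

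RA against DMSO asks what accompanies the duplication of proximodistal structures. CYP26A1, which oxidizes retinoic acid, had the largest rise among named genes, from a log2 level of 6.71 ± 2.16 (SD, n = 4) to 12.58 ± 0.15 in RA, a log2 fold change of 5.87 (SE 0.79, adjusted p = 0.00347). CYP26B1, a related oxidase, rose by 2.59 (SE 0.34) and DHRS3, a retinaldehyde reductase, by 2.25 (SE 0.26). The distal limb regulators LMO1, LHX9 and LHX2 fell, with log2 fold changes of -1.68 (SE 0.16), -1.52 (SE 0.19) and -1.26 (SE 0.15), and the proximal limb factors MEIS1 and MEIS2 rose by 0.94 (SE 0.09) and 1.03 (SE 0.17). In each of these genes the 4 RA samples lay on the same side of all 4 DMSO samples. The naming rule required this of all but MEIS1 and MEIS2, and 526 of the 528 probe sets that passed had it.

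Other genes with the largest rises were ACAN and BCAN, which encode the proteoglycans aggrecan and brevican, at 2.66 and 2.68, PAX6, a transcription factor, at 1.89, TGFB1, a growth factor, at 1.79, IGFBP6 at 1.75, the ammonium transporter RHBG at 1.73, the fibroblast protease FAP and the retinol dehydrogenase SDR16C5 at 1.60 each, and the glycosyltransferase B3GNT5 at 1.53. A second probe set of ACAN did not pass, at -0.17, nor did a second of BCAN, at 0.10. The largest fall was in MATN4, a cartilage matrix protein, at -2.86, followed by DOK4 at -2.11, the protease PRSS23 at -1.55, the water channel AQP3 at -1.53, the homeobox gene DLX6 at -1.38, ZIC5 at -1.35, the nuclease DNASE1L3 at -1.29, P2RY4 at -1.19 and the stress-induced factor DDIT3 at -1.19. ZIC5 stood at 3.91 in RA, near the lowest values of the arrays (3.05 to 3.15), so the size of its fall is uncertain. Second probe sets of AQP3, at 0.06, and DNASE1L3, at -0.79, did not pass, and of 2 other probe sets of MEIS2 the one at 0.84 passed and the one at 0.63 did not. Leaving out each sample in turn ended at least once the call of 20 of the 51 genes named here as rising or falling under RA, among them AQP3, DNASE1L3, P2RY4 and DDIT3 (adjusted p up to 0.0794, 0.0703, 0.0748 and 0.109).

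Of 26 measured genes of retinoid metabolism and receptors, 7 rose and 0 fell, 8 and 0 when adjusted over the list alone. Besides CYP26A1, CYP26B1 and DHRS3 these were the corepressor NRIP1 at 1.36, RARG (retinoic acid receptor gamma) at 0.70, the retinoic acid carrier CRABP2 at 1.28 and ALDH1A3, which makes retinoic acid, at 1.06. A second probe set of RARG did not pass, at 0.08. The list passed camera (adjusted p = 4.57e-05), with adjusted p = 0.182 with an estimated correlation. RARA differed by 0.12 (adjusted p = 0.529), and RARB and SHH were not among the named probe sets. The RARA level was low, at 3.72 in DMSO and 3.84 in RA, where the lowest values of the arrays were 3.05 to 3.15. Its values thus say little about a change in RARA.

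Of 24 distal limb genes, 7 fell and 2 rose, or 11 and 3 adjusted over the list alone. LMO1, DLX6, LHX2 and LHX9 had the smallest p of those that fell, and SPRY1, MSX2 and BMP7 were the other 3, at -0.75, -0.76 and -0.47. The 2 that rose were CYP26B1 and the ephrin receptor EPHA7, at 0.88. The list passed camera (adjusted p = 1.98e-04), with adjusted p = 0.182 with an estimated correlation. HOXA13, the homeobox gene of the hand and foot, stood at 4.45 ± 0.17 (SD, n = 4) in DMSO and 3.67 ± 0.20 in RA, a difference of -0.78 that did not pass (adjusted p = 0.118), and FGF8 differed by -0.70 (adjusted p = 0.503). The HOXA13 level in RA was as low as that of RARA, so the size of a fall could not be judged. Of 14 proximal limb genes 2 rose, MEIS1 and MEIS2, also 2 adjusted over the list alone. The list did not pass camera (adjusted p = 0.155) but passed fry (adjusted p = 0.0369).

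**Figure D1:**
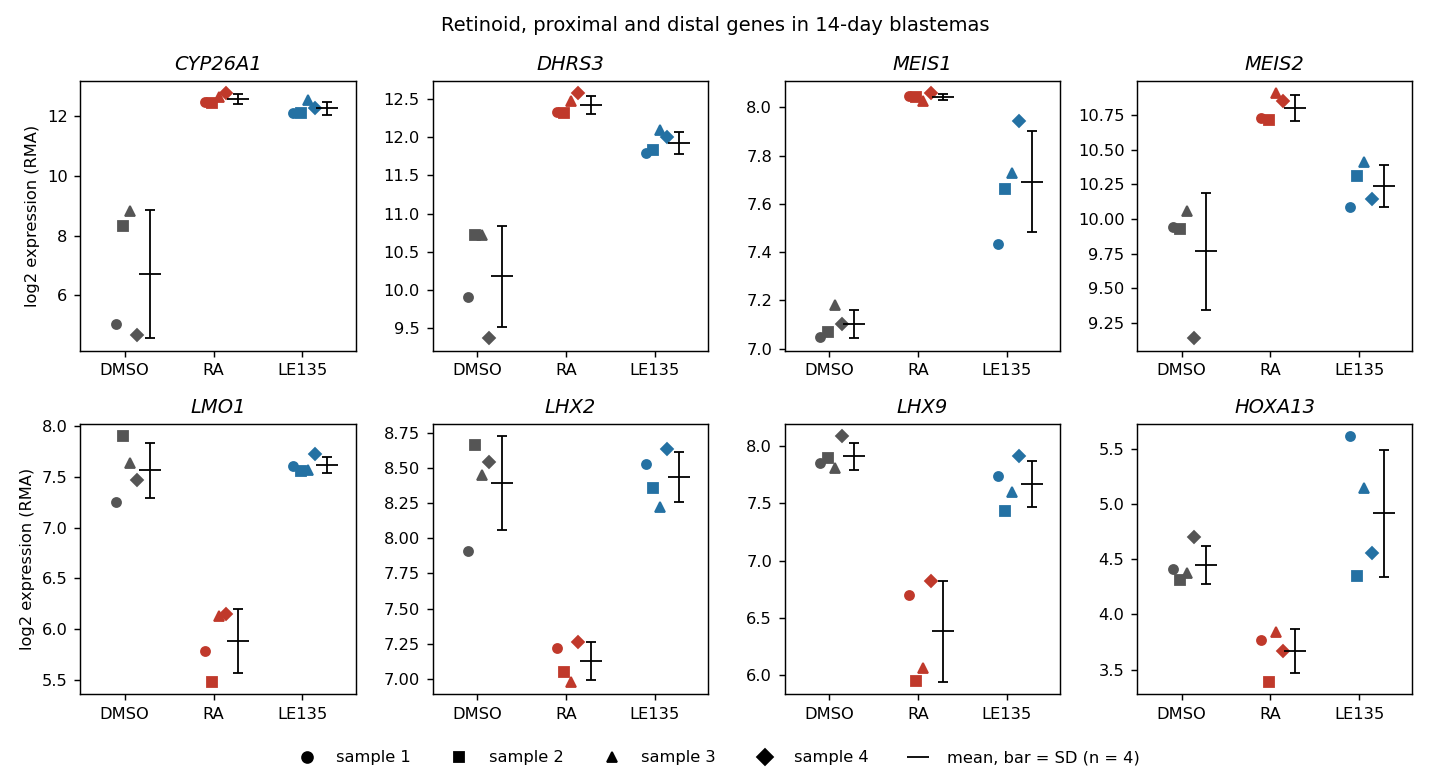
Log2 expression (RMA, vertical axis) of 8 genes in each of the 12 samples by treatment (horizontal axis), with a marker shape per sample number and a black mark for the mean with its SD (n = 4). CYP26A1, DHRS3, MEIS1 and MEIS2 lie higher in all 4 RA samples than in any DMSO sample, and LMO1, LHX2 and LHX9 lie lower, while the LE135 samples of LMO1 and LHX2 lie at the level of DMSO.

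Of 78 cell cycle genes, 5 fell and 2 rose under RA, or 36 and 3 adjusted over the list alone. KIF15 and ANLN fell, at -0.33 and -0.40, and BIRC5 and TOP2A rose, by 0.37 and 0.66. The list median was -0.25, and camera passed (adjusted p = 5.30e-13), with adjusted p = 0.182 with an estimated correlation. Without DMSO 4 and LE135 4, 26 of the 78 fell and 2 rose.

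Connective tissue, matrix and protease lists had few members past the threshold. Of 28 connective tissue fibroblast genes FAP and DCN rose, by 1.60 and 0.32, also 2 adjusted over the list alone (camera adjusted p = 3.61e-10, adjusted p = 0.182 with an estimated correlation). Of 31 matrix proteases and inhibitors FAP, ADAM9 (1.27) and BMP1 (0.49) rose, with 9 higher and 1 lower adjusted over the list alone (camera adjusted p = 9.89e-06, adjusted p = 0.182 with an estimated correlation). Of 58 extracellular matrix genes DCN rose and TNN, at -0.90, fell, also 1 and 1 adjusted over the list alone, and neither passed with the sample number as a block (adjusted p = 0.0823 and 0.0558) (camera adjusted p = 9.89e-06, adjusted p = 0.394 with an estimated correlation). Of 32 epidermis genes ST14 and AQP3 fell, at -0.43 and -1.53, with 4 lower adjusted over the list alone (camera adjusted p = 0.00309, adjusted p = 0.394 with an estimated correlation). Of 19 FGF pathway genes SPRY1, a feedback inhibitor of FGF signalling, fell, with 3 lower and 1 higher adjusted over the list alone (camera adjusted p = 0.0441, adjusted p = 0.182 with an estimated correlation and 0.0701 with the block). Of 39 oxidative phosphorylation genes CYCS fell, at -0.39 (adjusted p = 0.0687 with the block), also 1 adjusted over the list alone (camera adjusted p = 0.0305, adjusted p = 0.886 with an estimated correlation). The FGF pathway and oxidative phosphorylation lists did not pass camera without DMSO 4 and LE135 4 (adjusted p = 0.270 and 0.522).

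Muscle transcripts varied between samples of the same treatment. Of 45 skeletal muscle genes DES rose, by 0.92, with 2 higher adjusted over the list alone (camera adjusted p = 9.56e-05, adjusted p = 0.673 with an estimated correlation). The list score ran from -1.36 (DMSO 4) to 0.36 (DMSO 2) within DMSO and from -0.81 (RA 3) to 1.01 (RA 2) within RA. The list did not pass camera without DMSO 4 and LE135 4 (adjusted p = 0.0933).

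Other lists did not pass camera. Of 26 WNT pathway genes APCDD1 rose by 1.13 and LGR4 fell by 0.62. Of 33 genes of the BMP and TGF-beta pathway TGFB1 rose, and BMPR1B and BMP7 fell, at -0.82 and -0.47. Of 26 cartilage and bone genes ACAN rose and MATN4 fell, of 32 heat shock and unfolded protein response genes HSP90AB1 rose by 0.23 (adjusted p = 0.0561 with the block) and DDIT3 fell, of 23 inflammation genes IL6ST rose by 0.62 and TLR2 fell by 1.09, and of 14 pericyte and smooth muscle genes DES rose. No member passed among the hedgehog pathway, ribosomal protein, cholesterol biosynthesis, xenobiotic and oxidative stress response, interferon response, secretory epidermis and ion transport, erythrocyte, macrophage and neutrophil, lymphocyte, endothelium, Schwann cell and nerve, and pigment cell lists.

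In total 528 probe sets changed between RA and DMSO, 325 higher and 203 lower, and 296 of them more than 1.5-fold. They included 304 named genes. Groups did not overlap in 11.3% of all probe sets, where chance gives 2.86%. Without DMSO 4 and LE135 4 the count was 1530, of which 519 were among the 528. The count was 231 without RA 1 and 340 in a fit of the 8 compared samples alone.

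LE135 against DMSO asks what accompanies the truncation. CYP26A1 rose here as well, to 12.26 ± 0.20 (SD, n = 4), a log2 fold change of 5.55 (SE 0.79, adjusted p = 0.00524), DHRS3 rose by 1.75 (SE 0.26) and ALDH1A3 by 1.26 (SE 0.21). Cell cycle genes fell in number, among them ANLN, needed for cytokinesis, at -0.77, and MAD2L1, a spindle checkpoint protein, at -0.66. LMO1 and LHX2 stood within 0.05 of DMSO, at 0.05 (adjusted p = 0.944) and 0.05 (adjusted p = 0.947).

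Further large rises were in ACAN at 2.61, BCAN at 2.49, the epithelial transcription factor EHF at 2.18, the glycosyltransferases C1GALT1 at 1.68 and B4GALT3 at 1.24, the uroplakin UPK3A at 1.65, FAP at 1.39, RHBG at 1.32 and the phosphodiesterase SMPDL3B at 1.23. Other probe sets of ACAN (-0.28), BCAN (0.12) and UPK3A (0.18 and 0.19) did not pass. The largest falls were in DNASE1L3 at -1.70, the epidermal transglutaminase TGM1 at -1.63, DOK4 at -1.48, the BMP receptor BMPR1B at -1.38, DLX6 at -1.26, the protease inhibitor TFPI2 at -1.26, GPR37 at -1.20, DDIT3 at -1.19, NEBL at -1.14, UAP1 at -1.04, PTPRZ1 at -1.01 and RHOF at -1.01. A second probe set of TFPI2 fell by 1.39, and second probe sets of RHOF (0.44), DNASE1L3 (-0.64), UAP1 (-0.87) and PTPRZ1 (-0.56) did not pass. With the sample number as a block, TGM1 and DOK4 no longer passed (adjusted p = 0.0847 and 0.0508). Leaving out each sample in turn ended at least once the call of 18 of the 42 genes named here as rising or falling under LE135, among them TGM1, DOK4, GPR37, DDIT3, UAP1, PTPRZ1 and RHOF.

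Of the 26 retinoid genes 6 rose and 0 fell, or 9 and 3 adjusted over the list alone. The other 3 were RARG at 0.39, CRABP2 at 1.08 (adjusted p = 0.0638 with the sample number as a block) and NRIP1 at 0.45, whose calls ended in 9, 10 and 11 of the 12 omissions of 1 sample. A second probe set of RARG did not pass, at 0.06. CYP26B1, at 1.48 (SE 0.34), missed the threshold (adjusted p = 0.0505) and passed with the sample number as a block (adjusted p = 0.0212). The list passed camera (adjusted p = 0.00134), with adjusted p = 0.268 with an estimated correlation. RARA, again low at 3.77 in LE135, differed by 0.05 (adjusted p = 0.848).

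Of the 78 cell cycle genes 30 fell and 0 rose, or 52 and 0 adjusted over the list alone, by log2 fold changes from -0.77 to -0.30. NCAPG and NUSAP1, which act on chromosomes and the spindle, fell by 0.45 and 0.52. The list median was -0.34 and camera passed (adjusted p = 3.59e-30), with adjusted p = 0.0989 with an estimated correlation. Without DMSO 4 and LE135 4, 44 fell.

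Of the 32 epidermis genes 5 fell, or 9 lower and 1 higher adjusted over the list alone. They were ST14, TP63, JUP, TGM1 and DSC2, with TP63, the transcription factor of basal epidermis, at -0.81, and JUP did not pass with the block (adjusted p = 0.0569). Camera passed (adjusted p = 1.19e-06), with adjusted p = 0.268 with an estimated correlation. In the fit without DMSO 4 and LE135 4, 11 of the epidermis genes fell and 1 rose. Of the 31 matrix proteases and inhibitors FAP, ADAM9 (1.02) and MMP9 (0.37) rose, with 4 higher adjusted over the list alone (camera adjusted p = 0.00249, adjusted p = 0.418 with an estimated correlation). FAP was the 1 connective tissue fibroblast gene of 28 that rose, also 1 adjusted over the list alone (camera adjusted p = 0.00710, adjusted p = 0.893 with an estimated correlation). No skeletal muscle gene of 45 passed, also 0 adjusted over the list alone (camera adjusted p = 0.00710, adjusted p = 0.980 with an estimated correlation). The protease, connective tissue fibroblast and skeletal muscle lists did not pass camera without DMSO 4 and LE135 4 (adjusted p = 0.257, 0.152 and 0.749), and the skeletal muscle median was then 0.04, against 0.32 with them.

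DLX6 was the 1 distal limb gene of 24 that fell and none rose, with 2 lower and 1 higher adjusted over the list alone (camera adjusted p = 0.932). LHX9 differed by -0.24 and HOXA13 by 0.47 (adjusted p = 0.429). Of 14 proximal limb genes MEIS1 rose, by 0.59 (SE 0.09, adjusted p = 0.00675), also 1 adjusted over the list alone (camera adjusted p = 0.284). MEIS2 differed by 0.47 (adjusted p = 0.236) and FGF8 by 0.10 (adjusted p = 0.960).

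**Figure D2:**
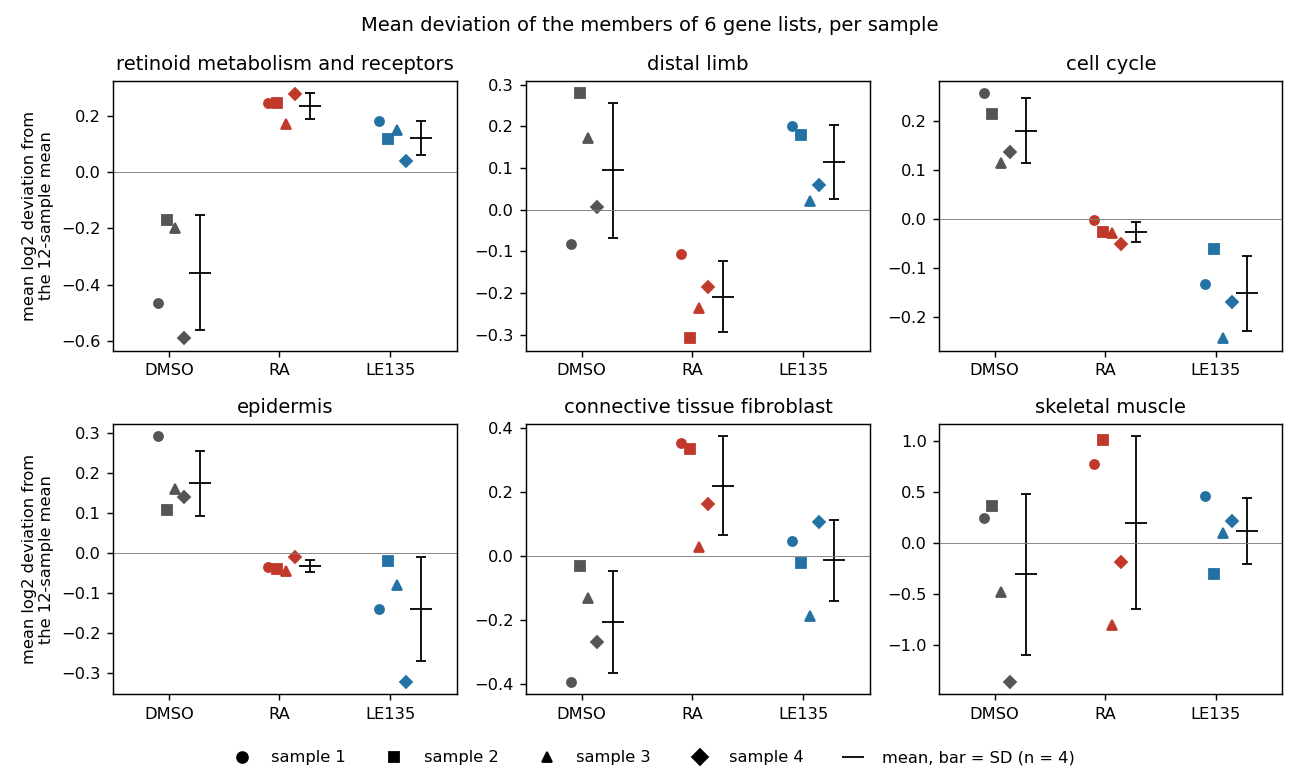
Mean log2 deviation of the members of 6 gene lists from each gene's mean over the 12 samples (vertical axis), per sample and treatment (horizontal axis), with the mean and SD (n = 4) in black. The cell cycle score is lower in every RA and LE135 sample than in any DMSO sample, and the skeletal muscle score spreads from -1.36 to 1.01.

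Other lists did not pass camera. Of 26 cartilage and bone genes ACAN and SP7, an osteoblast transcription factor, rose, the latter by 0.73. BMPR1B fell among 33 genes of the BMP and TGF-beta pathway. Of 29 macrophage and neutrophil genes MMP9 and CYBA rose, the latter by 0.40, and SPI1 fell by 0.60. HSP90AB1 rose by 0.22 (adjusted p = 0.0757 with the block) and DDIT3 fell among 32 heat shock and unfolded protein response genes. No member passed in the FGF pathway, extracellular matrix or oxidative phosphorylation lists.

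In total 418 probe sets changed between LE135 and DMSO, 179 higher and 239 lower, and 226 of them more than 1.5-fold. They included 238 named genes. Groups did not overlap in 7.53% of all probe sets, where chance gives 2.86%. The count was 1027 without DMSO 4 and LE135 4, of which 380 were among the 418. It was 742 without DMSO 4 alone, 220 without LE135 1 and 111 in a fit of the 8 compared samples.

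RA against LE135 compares blastemas with different outcomes. The distal limb genes LMO1 and LHX2 and the FGF inhibitor SPRY1 were lower in RA, by log2 differences of -1.73 (SE 0.16, adjusted p = 0.00518), -1.31 (SE 0.15, adjusted p = 0.0185) and -0.75 (SE 0.10, adjusted p = 0.0485). NRIP1, a corepressor that binds retinoic acid receptors, was higher in RA by 0.91 (SE 0.10, adjusted p = 0.0184). The 4 samples of each group did not overlap in any of them, which the naming rule required. No other probe set passed, and 1537 had an unadjusted p under 0.05. SPRY1 lost the threshold with the replicate block (adjusted p = 0.0733) and with a trended robust prior (adjusted p = 0.0507). Leaving out LE135 1, among other samples, ended the calls of NRIP1, LHX2 and SPRY1 (adjusted p = 0.123, 0.124 and 0.197), and no omission of 1 sample ended that of LMO1 (adjusted p at most 0.0433).

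Of the 24 distal limb genes these 3 were the ones that fell, with 7 lower and 2 higher adjusted over the list alone (camera adjusted p = 9.68e-05, adjusted p = 0.392 with an estimated correlation). LHX9 differed by -1.29 (adjusted p = 0.0652, and 0.0281 with the block) and HOXA13, whose level in RA was low, by -1.25 (adjusted p = 0.127). Camera passed with no member past the threshold for cell cycle genes, higher in RA with a median of 0.13 (adjusted p = 3.18e-11, adjusted p = 0.392 with an estimated correlation), and for extracellular matrix (adjusted p = 5.76e-06, adjusted p = 0.538 with an estimated correlation). It did so as well for connective tissue fibroblast (adjusted p = 8.22e-06, adjusted p = 0.521 with an estimated correlation) and epidermis genes (adjusted p = 0.0367, adjusted p = 0.665 with an estimated correlation), the latter not without DMSO 4 and LE135 4 (adjusted p = 0.245). Adjusted over the list alone, 0 members passed in each of these 4 lists. MEIS1 and MEIS2 differed by 0.35 (adjusted p = 0.296) and 0.56 (adjusted p = 0.404), RARG by 0.31 (adjusted p = 0.332), CYP26B1 by 1.11 (adjusted p = 0.404) and CYP26A1 by 0.32 (adjusted p = 0.956). FGF8 differed by -0.79 (adjusted p = 0.734) and RARA by 0.07 (adjusted p = 0.898). These tests use a spread shared by all 3 groups, DMSO included. For CYP26A1 the SD was 2.16 in DMSO, 0.15 in RA and 0.20 in LE135, and the SE was 0.79. Its p-value thus says little about whether the 2 drugs differ. Without DMSO 4 and LE135 4, 43 probe sets differed between the drugs, the 4 genes among them. The count was 186 with array weights and 11 with the block. It ran from 1 (without RA 2) to 13 (without DMSO 4) when samples were left out in turn.

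The responses to the 2 drugs were compared across probe sets. Of the 12 largest rises and 12 largest falls per drug, CYP26A1, ACAN, BCAN, DHRS3, FAP and RHBG rose and DOK4, DLX6, DNASE1L3 and DDIT3 fell under both. Other named genes changed under both as well, among them MEIS1, RARG, ADAM9, BMPR1B and ANLN. UPK3A and UAP1, named for LE135, also passed under RA, at 1.19 and -0.97, but were not followed there through the alternatives. Under RA other probe sets of UPK3A (-0.39 and 0.04) did not pass and that of UAP1 (-1.06) did. In all, 111 probe sets rose and 93 fell under both drugs, where independent lists of these lengths would share 2.90 and 2.42, and 0 changed in opposite directions. With the DMSO samples divided between the comparisons, the shared calls numbered at least 47, where independent lists would share at most 2.53. The log2 fold changes correlated across probe sets with r = 0.722 (genes are not independent replicates), within the range of 100 simulations of unchanged groups sharing the DMSO samples (median 0.548, from -0.240 to 0.961 for the central 95%). The covariance was 0.0476, and the simulated values had a median of 0.0145 and ran from -0.0055 to 0.0572. With divided DMSO samples r averaged 0.309, from 0.0872 to 0.523.

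**Figure D3:**
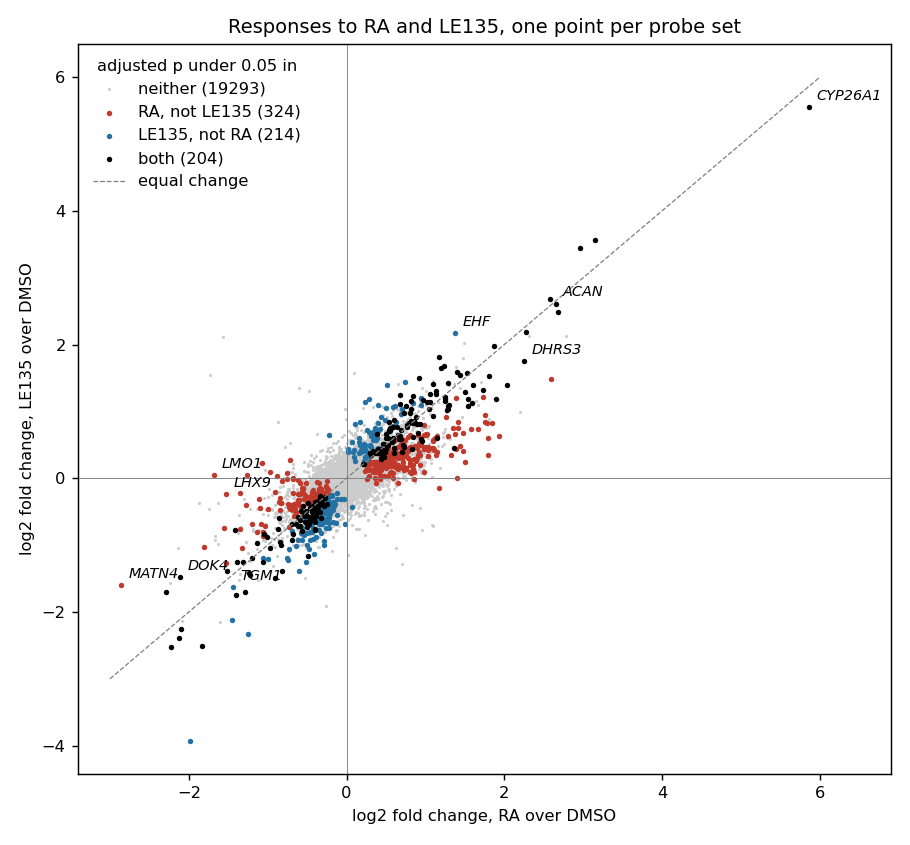
Log2 fold change of each probe set under RA (horizontal axis) and LE135 (vertical axis), both over DMSO, coloured by the comparison in which the adjusted p was under 0.05, with a dashed line of equal change. The 204 probe sets past the threshold under both drugs lie in the upper right and lower left, and LMO1 lies near 0 for LE135 and at -1.68 for RA.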

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

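Of the tests in this part, those of an exchange of samples, of the poly-A controls, of the shared DMSO samples, of mixed RNA, of stump tissue, of the share of epidermis and of the cell cycle list without DMSO 4 and LE135 4 were chosen only after the result was seen.

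In 19 of 231 groups of 4 samples, 1 sample lay far from the other 3 (Dixon's test), where chance gives about 1 in 20. DMSO 4 was that sample in 7 groups and LE135 4 in 4. Among named genes these were ACAN in DMSO 4 at a log2 level of 7.764 (others 8.979 to 9.085), DOK4 in DMSO 4 at 9.236 (7.598 to 7.827), P2RY4 in DMSO 4 at 9.628 (8.330 to 8.509), MEIS2 in DMSO 4 at 9.139 (9.926 to 10.060), DLX6 in LE135 4 at 6.798 (6.969 to 7.003), and UAP1 in LE135 4 at 9.364 (10.143 to 10.268). The others were CYP26B1 in RA 1 at 9.826 (9.514 to 9.564), ZIC5 in DMSO 2 at 5.717 (5.099 to 5.119), SMPDL3B in LE135 1 at 9.568 (9.798 to 9.811) and RHOF in DMSO 1 at 10.057 (9.387 to 9.477).

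In 6 list scores a sample lay far from the rest: secretory epidermis and ion transport in DMSO 4 at -0.533 (0.175 to 0.263), pigment cell in DMSO 4 at -0.204 (0.065 to 0.091), heat shock and unfolded protein response in DMSO 4 at -0.052 (0.082 to 0.098), FGF pathway in RA 2 at -0.146 (-0.114 to -0.111), matrix proteases and inhibitors in LE135 3 at -0.205 (0.047 to 0.096), and interferon response in LE135 2 at 0.273 (-0.045 to -0.006). The poly-A control probe sets, spiked into RNA before labelling by general knowledge of these arrays, averaged 6.466 in LE135 4 (7.696 to 7.901) and 7.149 in RA 1 (7.674 to 7.727). The hybridisation controls averaged 11.135 in LE135 4 (11.378 to 11.383).

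DMSO 4 and LE135 4 stood apart, with 1265 and 634 probe sets more than 2-fold from their group, against at most 162 in the other 10. They also deviated together, with r = 0.607 between their deviations from the group means. DMSO 4 correlated at 0.985 with LE135 4 and at 0.976 to 0.980 with the other DMSO samples. LE135 4 correlated at 0.984 to 0.988 with the other LE135 samples. What the 2 samples share was not tested. An exchange between the groups was argued against: on a scale from DMSO (0) to LE135 (1), LE135 4 lay at 1.265 and DMSO 4 at 0.455. Muscle content was argued against, since slopes on the muscle score accounted for -7.6% and 2.1% of the squared deviation of DMSO 4 and LE135 4. RNA input or labelling is a candidate explanation for LE135 4, whose poly-A controls lay -1.31 from the group (at most -0.551 in the other 10). For DMSO 4, at -0.515, it stays open: of the other 10 only RA 1, at -0.551, lay further out. No biological explanation was tested.

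RA and LE135 called 204 probe sets in common, although 1 is a ligand and the other is held to be an antagonist of the receptors. The shared DMSO samples as the whole cause were argued against by at least 47 shared calls with separate DMSO pairs, where at most 2.53 were expected, and DMSO 4 alone by 280 shared calls without it. RNA of RA blastemas in the LE135 samples stays open: the median share of the RA response in LE135 differed by 0.623 between 7 retinoid genes and 7 distal limb genes, with an exact p of 0.0583. A second test, added after the first was seen, put the distal genes 0.287 (SD 0.079) above the level of a mixture, but it rests on the 7 genes picked for falling under RA, with an SD that leaves out the error of the RA and DMSO means. An effect of LE135 on retinoid genes, a biological explanation, also stays open and was not tested.

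Cell cycle genes were lower under LE135, 30 of 78 past the threshold. Muscle content was argued against, since the list median was -0.356 with the muscle score in the model and -0.345 without, and so were DMSO 4 and LE135 4, since 44 genes fell without them. A larger share of stump tissue cannot be told apart: its lists should all be higher. The lowest median, of cartilage and bone, was -0.079 (SE of the list mean 0.151 over genes and 0.171 over samples). Endothelium was lowest without DMSO 4 and LE135 4, with a mean of -0.24 (SE over samples 0.13, over genes 0.08), and with all samples its mean was -0.11 (SE over samples 0.14), each within 2 SE over samples of 0. With all samples the Schwann cell and nerve mean was -0.009 (SE over samples 0.024), which shows no rise. The skeletal muscle mean was 0.43 (SE over samples 0.43). A smaller share of epidermis, whose genes were lower as well (29 of 32 below 0, 5 past the threshold), cannot be told apart either, since the mean of the cell cycle list minus that of the epidermis list was -0.018 (SE over samples 0.074). The list was lower under RA as well, whose limbs duplicate, with a median of -0.25. There 5 genes fell and 2 rose, or 36 and 3 adjusted over the list alone. Between RA and LE135 no member passed, with a median 0.13 higher in RA. Slower proliferation on the way to a truncated limb, a biological explanation, was not tested.

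Chance can be excluded for the count of probe sets in RA against DMSO, and for those among the treatments if the sample numbers are ignored. The numbers were treated as pairing LE135 and DMSO samples, although only pair 4 stood out. Among 100 splits of the 12 samples into 3 groups, only the real one, 1 split, reached 537 (highest other 154) or 329 (highest other 100). Among the 35 splits of 8 samples, 1 split, the real one, reached 528 for RA against DMSO (highest other 1) and 4 for RA against LE135 (highest other 1). For RA against LE135 this met the limit set beforehand, a share of splits under 0.05. Without RA 2 that count fell to 1, as many as in the highest other split, so chance is not firmly excluded there. For LE135 against DMSO 1 of 35 splits, the real one, reached 418 (highest other 2), so chance can be excluded if the sample numbers are ignored. With LE135 and DMSO samples paired by number, 8 splits part all 4 pairs, too few for a share under 0.05, with 418 in the real one and at most 0 calls in the others. Chance cannot be excluded for the numbers of lists past camera: 7, 16 and 22 of 35 splits gave as many as the real 10 (RA against DMSO), 6 (LE135 against DMSO) and 5 (RA against LE135), and the highest other was 13 in each.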

How the results depend on the processing

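Leaving out both DMSO 4 and LE135 4, and keeping the control probe sets, were chosen after seeing the data. No gene named as rising or falling, and no list past camera, changed direction under the alternatives run. Small medians of lists that did not pass did, such as cartilage and bone under LE135, at -0.08 with all samples and 0.09 without DMSO 4 and LE135 4. Counts are given in the order differing among treatments, also over 1.5-fold, RA against DMSO, LE135 against DMSO and RA against LE135, in the report 537, 329, 528, 418 and 4.

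Each count stayed within 1.5 times with a trended robust prior, quantile normalization, shifted medians, or without the dimmest 25% or 50% of probe sets. Array weights gave 1639, 602, 1362, 1265 and 186, and leaving out DMSO 4 and LE135 4 gave 1478, 575, 1530, 1027 and 43. An ordinary ANOVA gave 310, 175, 343, 301 and 2. The cause was not tested. The 8 compared samples alone, fewer samples, gave 340, 111 and 10 for the 3 contrasts, and a 1.5-fold limit left 296 and 226 for the drugs against DMSO. Limits of 1.2-fold and 2-fold gave 529 and 144 in place of 329. Control probe sets kept gave 533 and 326.

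The replicate block included the RA samples, which did not meet the rule for pairing. With it, RA against LE135 had 11 calls, 3 of them among the 4. DCN, TNN, CYCS, HSP90AB1 and the FGF pathway list under RA, TGM1, DOK4, CRABP2, JUP and HSP90AB1 under LE135, and SPRY1 between the drugs lost the threshold, and CYP26B1 under LE135 and LHX9 between the drugs passed. The block changed no other call of a gene named as rising or falling or of a list past camera, though other list members passed.

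Leaving out each sample in turn gave 261 (without RA 1) to 700 (without DMSO 4), 195 (without RA 1) to 405 (without DMSO 4), 231 (without RA 1) to 671 (without LE135 4), 220 (without LE135 1) to 742 (without DMSO 4) and 1 (without RA 2) to 13 (without DMSO 4). Lists past camera numbered 7 to 10 under RA, 3 (without DMSO 4) to 8 (without DMSO 2) under LE135 and 4 (without DMSO 4) to 8 (without RA 3) between the drugs. Of the named genes, 20 of 51 under RA lost the threshold at least once: AQP3, DNASE1L3, P2RY4, DDIT3, CRABP2, ALDH1A3, MSX2, BMP7, TNN, DCN, BMP1, KIF15, ANLN, BIRC5, TOP2A, CYCS, HSP90AB1, IL6ST, ST14 and DES. Under LE135 18 of 42 did: TGM1, DOK4, GPR37, DDIT3, UAP1, PTPRZ1, RHOF, RARG, CRABP2, NRIP1, MMP9, HSP90AB1, ST14, TP63, JUP, DSC2, CYBA and SPI1. Between the drugs 3 of 4 did, NRIP1, LHX2 and SPRY1.

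With an estimated correlation 0, 0 and 0 lists passed in the 3 contrasts. Fry gave 8, 3 and 1, leaving the distal limb list between the drugs. Under RA fry passed the proximal limb (adjusted p = 0.0369) and Schwann cell and nerve lists (adjusted p = 0.0134), which did not pass camera. It did not pass the extracellular matrix, oxidative phosphorylation, epidermis and skeletal muscle lists, which passed camera. Without the dimmest 25% of genes 8 lists passed between the drugs, and without DMSO 4 and LE135 4 the lists under LE135 numbered 3, retinoid, cell cycle and epidermis. The correlation of the responses was 0.309 with the DMSO samples divided, where noise of separate DMSO pairs is not shared, and 0.676 to 0.775 leaving out samples in turn.

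With medians shifted, BMP7, DCN, ANLN and HSP90AB1 under RA and DOK4, DDIT3, RHOF, RARG, NRIP1, HSP90AB1, JUP and DSC2 under LE135 lost the threshold, and LHX9 passed between the drugs. With the trended prior BMP7 and DCN under RA, NRIP1 and SPI1 under LE135 and SPRY1 between the drugs lost it, and CYP26B1 under LE135 passed. BMP1 under RA lost it without DMSO 4 and LE135 4, where CYP26B1 under LE135 and MEIS2 between the drugs passed. The number of samples per group, 4, limits what can be called, and signal over background could not be assessed without detection calls.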

Other observations

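Within RA, samples 1 and 2 correlated at 0.997 and samples 3 and 4 at 0.998, against 0.991 to 0.995 between these pairs. The difference of samples 1 and 2 from sample 3 within RA correlated across probe sets with the same difference within DMSO (r = 0.24) and within LE135 (r = 0.20), in a test planned before its result was seen. Sample 4 of each group was left out of that test. The values left open whether the sample numbers share a batch.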
